A study of Mus musculus with 8 samples.

How the data were processed

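The series measured RNA from whole cerebellum of mice at 28 days of age, 4 wild-type animals and 4 animals with a mutation of Capicua (Cic), a transcriptional repressor that binds DNA and forms a complex with ataxin-1. The genotype label of the mutants is Cic-L-null, and their titles read Cicnull. The strain label of all 8 animals is a mixed background of Swiss Webster (CD-1). Each animal's RNA was hybridised to 1 Affymetrix Mouse Gene 1.0 ST array, per the labels' protocols. The label of wild-type replicate 1 names a Trizol and RNeasy extraction, whereas those of the other 7 arrays name only the manufacturer's standard protocol. Samples were assigned to groups from their titles, which also number the replicates 1 to 4 in each group.

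The deposited table holds log2 expression values, which the authors made with RMA (background correction, quantile normalisation and summarisation) in the Affymetrix Power Tools, per the submitters' processing notes; versions, library files and genome build are not given in the sources used here. The table lists 241576 probe sets, a number that lies below the level of genes, with 0 missing values. The median log2 value per array lay between 7.82 and 7.88. Arrays give no read depth, and the small number of animals limits the precision, beside other limits given below.

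Gene names came from the platform annotation deposited for the array, which is old. Of the probe sets, 212097 carried 1 gene symbol, 4475 carried several and 25004 carried none in that annotation, and only those with 1 symbol entered a gene. Of the 20416 symbols, 17621 were current in the gene table of assembly GRCm38.p6, 2742 were replaced through a synonym that belongs to 1 gene, and 53 were kept as given. The gene value was the mean log2 value of its probe sets, which gave 20352 genes with a median of 8 probe sets each, and 2259 genes rested on 1 probe set. The build behind the annotation is not stated, so no coordinates are printed, and GRCm38.p6 served only for names and for which genes lie near Cic.

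Gene values were compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), a moderated test in both directions with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. No filter on dim genes was applied, and the group was the only term. The same fit over all 241576 probe sets gave probe set calls. All differences are log2 values of Cic-L-null minus wild-type. The labels describe the 4 samples of a group as separate animals.

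A total of 27 gene lists were written before the data were examined, covering Capicua targets, partners of Capicua and ataxin-1, markers of the cell types of cerebellum and its surroundings, and pathways. The Capicua target list was compiled from general knowledge of the protein, in part from studies of mutant mice, so its direction was anticipated. Part of that published work may have used these same samples. Lists of sex-linked genes and reference genes were not tested as sets. The other 25 lists, with 459 of 492 members measured, were tested with camera of limma with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 25. Camera with an estimated correlation and fry were alternatives. Members absent from the gene values are not analysed here. Genes within 20 Mb of Cic were tested for an excess of calls with Fisher's exact test.

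The genes named in the text followed a rule set at the same time. It takes Cic, Atxn1, Atxn1l, Etv1, Etv4 and Etv5 in any case. It takes the 12 largest rises and the 12 largest falls among called genes whose 4 mutant arrays lie on 1 side of all 4 wild-type arrays. From each list it takes up to 4 members with the smallest p, applied as 4 for lists past the threshold and 2 for the others, and it takes the sex-linked genes. A gene outside the rule is marked in the text as chosen after its value was seen.

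On simulated data made from these gene values, with 200 of 20352 genes changed, the fit recovered 69.8% of changes of 0.5 log2 units and 97.7% of changes of 1 log2 unit. With no change simulated it called 0 genes in 10 simulations. Camera found 20 of 20 simulated lists shifted by 0.2 log2 units and called 2 of 480 unshifted ones. The simulated genes varied independently of each other, whereas the estimated correlation within the real lists reached 0.67. The simulation therefore does not give the rate of false list calls in these data.

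Alternatives covered how probe sets were combined, 2 limits on dim values taken from 985 olfactory receptor genes, other normalisations, the variance model, array weights, a replicate block, a covariate of Y-linked genes, a covariate from the first principal component of the residuals, the threshold, the test and each array left out in turn. The closing sections give their effect.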

Results

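Gene expression was profiled in the cerebellum of 28-day-old mice, 4 wild-type animals and 4 Capicua mutants, with 1 array per animal. The series has a single comparison, mutant against wild-type, which asks which transcripts of the cerebellum depend on Capicua, a repressor of genes downstream of receptor tyrosine kinase signalling. Gene values correlated between 0.9913 and 0.9954 across all pairs of arrays. The first principal component held 28.5% of the variance and did not separate the groups, whereas the second, with 18.3%, had all 4 wild-type arrays below all 4 Cic-L-null arrays. Wild-type replicates 1 and 4 and Cic-L-null replicates 1, 2 and 4 had high log2 values of the Y-linked genes Kdm5d, Eif2s3y and Uty and low values of Xist, the RNA of the inactive X chromosome. The other 3 arrays had the reverse pattern. The wild-type group thus held 2 arrays with Y-linked signal and the mutant group 3.

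Cic, the altered gene, was lower in every mutant than in every wild-type cerebellum. Its log2 value was 8.78 ± 0.28 (SD, n = 4) in wild-type and 7.54 ± 0.061 (SD, n = 4) in Cic-L-null mice, a difference of -1.25 (SE 0.12, adjusted p = 0.00818 with limma) or 2.37-fold. All 21 Cic probe sets had a lower mean in the mutants, 17 of them with no overlap between the groups. The median of the 21 differences was -1.32. Probe set 10551086 showed the lowest difference at -2.40 (SE 0.32), whereas probe set 10551081 differed by -0.085 (SE 0.14) with overlapping groups. The files do not say which part of the transcript each probe set covers. Tested among all 241576 probe sets, none of the 21 passed the threshold, and the smallest adjusted p was 0.129. The gene-level call was lost when Cic-L-null replicate 2 was left out, with a difference of -1.23 and an adjusted p of 0.0589, and with the replicate numbers as a block (-1.25, adjusted p = 0.0564) or unmoderated tests (-1.25, adjusted p = 0.157).

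**Figure D1:**
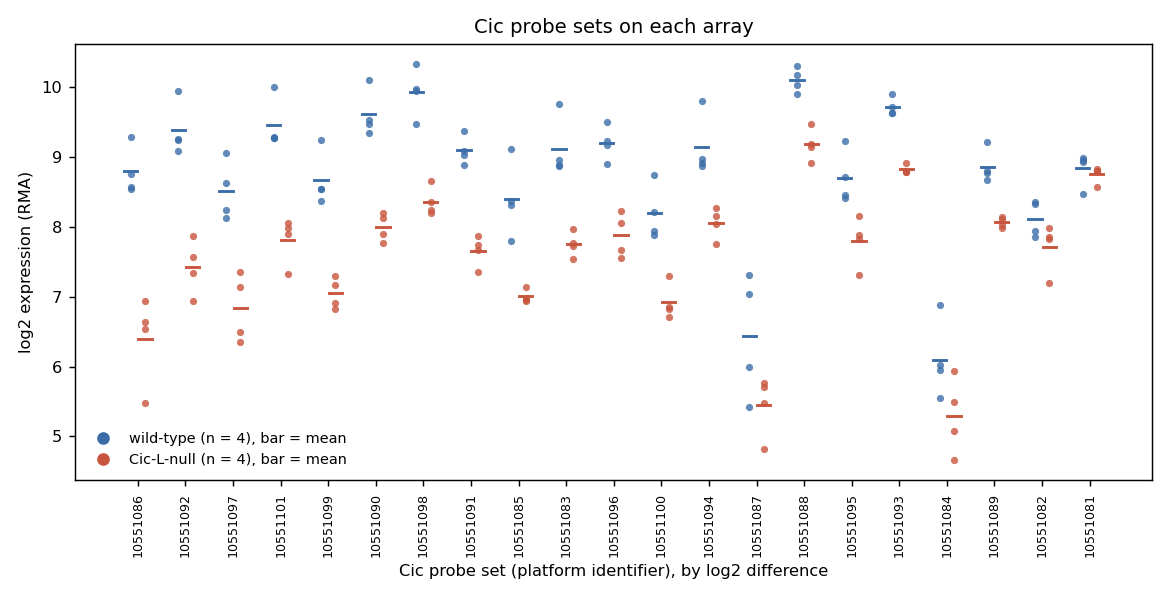
Log2 expression (vertical axis) of the 21 Cic probe sets (horizontal axis, ordered by difference) on each of the 8 arrays, with points for arrays and bars for group means of 4 wild-type and 4 Cic-L-null cerebella. The mutant mean lies below the wild-type mean for all 21 probe sets, with differences from -0.085 to -2.40.

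Across the genome the mutant cerebellum differed in 28 genes, 18 higher and 10 lower, and each of the 28 had no overlap between the groups. Dusp4 rose by 0.94 (SE 0.14), from 6.68 ± 0.21 to 7.62 ± 0.26 (SD, n = 4), and Dusp6 rose by 0.49 (SE 0.076). Both are on the list of Capicua targets and encode phosphatases that inactivate MAP kinases. Fabp7, a fatty acid binding protein of radial and Bergmann glia, fell by 1.17 (SE 0.14), from 10.39 ± 0.27 to 9.22 ± 0.21 (SD, n = 4), the largest fall after Cic.

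Genes of the circadian clock or its output were among the rises. Per2 rose by 0.75 (SE 0.11), Nr1d1 by 0.66 (SE 0.078), Dbp by 0.64 (SE 0.090) and Per3 by 0.60 (SE 0.075). Per2 and Per3 are period genes, Nr1d1 is a nuclear receptor that represses the clock gene Arntl, and Dbp is a transcription factor whose RNA cycles strongly over the day. The clock was not among the lists set in advance, these 4 genes entered by the size of their change, and the labels give no time of day at which tissue was collected.

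Hsd11b1, which encodes the enzyme that regenerates active glucocorticoid, rose by 0.69 (SE 0.065, adjusted p = 0.00818), and the long non-coding RNA Mirt1 rose by 0.68 (SE 0.079). Genes of ion transport included the sodium channel gene Scn11a, higher by 0.66 (SE 0.087), and the plasma membrane calcium pump gene Atp2b4, higher by 0.52 (SE 0.071). Scn11a lay at 6.15 in wild-type, below the limit of 6.21 that olfactory receptor genes set for dim genes. Its difference was as low as 0.43 over the alternatives. Cables1, a partner of cyclin-dependent kinases, was higher by 0.58 (SE 0.084). The carbonic anhydrase gene Car9 and the synapsin gene Syn3 were each higher by 0.52, with SE 0.064 and 0.070.

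Among the falls, Top2a, a topoisomerase of dividing cells, fell by 0.56 (SE 0.067), with 32 of its 40 probe sets lower and a median probe set difference of -0.36. Its size depended on how probe sets were combined, at -0.94 with their median as gene value and -0.40 with only those above the dim limit, and it was not called with either. Pmp22, a peripheral myelin protein gene that is not on the list of oligodendrocyte markers, fell by 0.45 (SE 0.065). Klk6, a protease gene of oligodendrocytes, fell by 0.66 (SE 0.090), and Cd59a, which encodes an inhibitor of the complement attack complex, fell by 0.65 (SE 0.071). Sema3c, a secreted guidance cue, fell by 0.47 (SE 0.065), and Agmo, an ether lipid enzyme gene, fell by 0.52 (SE 0.081). Sergef and Luzp2 fell by 0.72 (SE 0.10) and 0.49 (SE 0.067). Both lie on the chromosome that carries Cic, as do Klk6 and Dbp. All 17 probe sets of Luzp2 were lower, with a median of -0.31, and 1 of them fell by 3.21.

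Of the members of the complex other than Cic, Atxn1 differed by 0.078 (SE 0.082) and Atxn1l, its paralogue, by 0.020 (SE 0.061). The PEA3 transcription factor genes Etv1, Etv4 and Etv5, which Capicua is known to repress, differed by 0.16 (SE 0.081), 0.34 (SE 0.086) and 0.18 (SE 0.078). None of these 5 passed over all genes, with adjusted p of 0.211 for Etv4 and above it for the others.

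**Figure D2:**
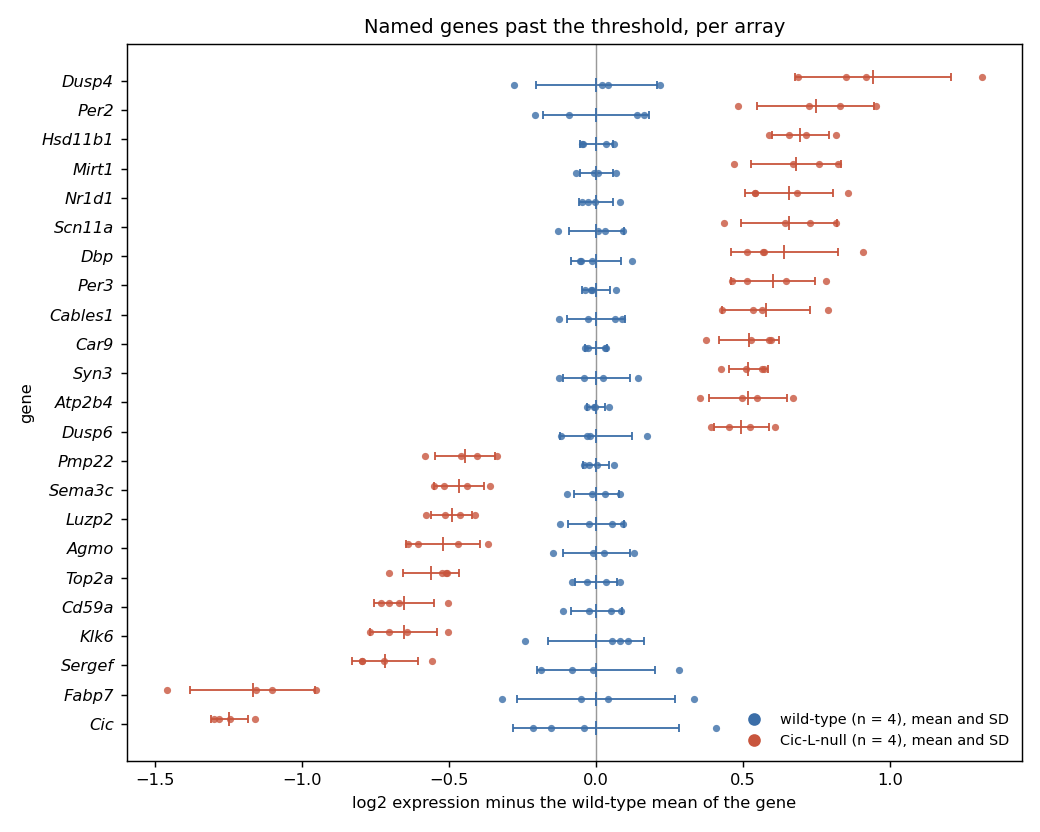
Log2 expression minus the wild-type mean (horizontal axis) of the 23 named genes past the threshold (vertical axis), with a point per array and bars for the mean and SD of 4 wild-type and 4 Cic-L-null cerebella. The points of the groups do not overlap for any of the genes shown, from a difference of 0.94 for Dusp4 to -1.25 for Cic.

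Calls were made with limma at an adjusted p under 0.05 over 20352 genes, where 1885 had an unadjusted p under 0.05. In all, 1208 genes (5.94%) had groups that did not overlap, against 2.86% given by chance for 4 against 4. The count of calls moved with single arrays, from 0 without Cic-L-null replicate 2 to 3 without wild-type replicate 2, wild-type replicate 3 or Cic-L-null replicate 4. It was 5 without wild-type replicate 4, 7 without Cic-L-null replicate 1, 36 without Cic-L-null replicate 3 and 37 without wild-type replicate 1. All 28 genes kept their sign each time, but groups that do not overlap fix this in advance, so it is no sign of stability. Other settings also moved the count. It was 2 with the median of the probe sets as gene value, 12 with their brighter part, 18 with a covariate of Y-linked genes, 69 among genes above the dim limit, 54 with array weights, 130 with a trended and robust variance, 0 with unmoderated tests and 0 with the replicate numbers as a block.

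The list of Capicua targets rose as a group. Of its 29 measured members, 24 had a difference above 0, with a median of 0.18 (camera adjusted p = 1.79e-15; adjusted p = 0.0844 with an estimated correlation). Dusp4, Per2 and Dusp6 rose over all genes, and 14 members rose when adjusted over the list alone, Etv4 among them. Per2 is also a clock gene, and its rise may belong to the clock pattern instead. Vgf, a neuropeptide precursor induced by growth factors, differed by 0.50 (SE 0.083) with an adjusted p of 0.0582 over all genes. The list was written with the direction of change in mind, since many of its genes are known to be repressed by Capicua.

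Markers of mature oligodendrocytes passed as a list with the preset correlation, in the direction of lower values. Of 20 measured members, 19 had a difference below 0, with a median of -0.13 (camera adjusted p = 1.45e-06; adjusted p = 0.20 with an estimated correlation). No member passed over all genes, and 4 fell when adjusted over the list alone. These were the myelin genes Mobp at -0.30 (SE 0.060) and Cldn11 at -0.21 (SE 0.057), the transferrin gene Trf at -0.33 (SE 0.076) and Ndrg1 at -0.29 (SE 0.091). The 16 precursor markers of the same lineage went both ways, 8 above and 8 below 0, with Vcan at 0.47 (SE 0.089) and Enpp6 at -0.23 (SE 0.080).

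Cell cycle genes passed as a list with the preset correlation only, with 16 of 20 members below 0 and a median of -0.11 (camera adjusted p = 3.93e-05; adjusted p = 0.435 with an estimated correlation). Top2a fell over all genes, and 5 members fell when adjusted over the list alone, among them the proliferation marker Mki67 at -0.23 (SE 0.067), Rrm2 at -0.27 (SE 0.080) and the spindle checkpoint gene Bub1 at -0.24 (SE 0.078). The wild-type log2 values of these 4 genes, from 4.8 for Bub1 to 6.16 for Rrm2, lie below the dim limit of 6.21 that olfactory receptor genes set. Mki67 also lies on the chromosome of Cic. There 1 of its 16 probe sets differed by -1.31, and the others had a median of -0.13.

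Genes of cholesterol biosynthesis passed as a list with the preset correlation only, with 13 of 16 members below 0 and a median of -0.17 (camera adjusted p = 0.00600; adjusted p = 0.751 with an estimated correlation). No member passed over all genes or over the list alone. Msmo1 differed by -0.30 (SE 0.11), Hmgcs1 by -0.23 (SE 0.092), Sqle by -0.22 (SE 0.090) and Idi1 by -0.28 (SE 0.12). The call was lost without wild-type replicate 1 (adjusted p = 0.0868), without Cic-L-null replicate 4 (median -0.058, adjusted p = 0.223) and with array weights (adjusted p = 0.0986).

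**Figure D3:**
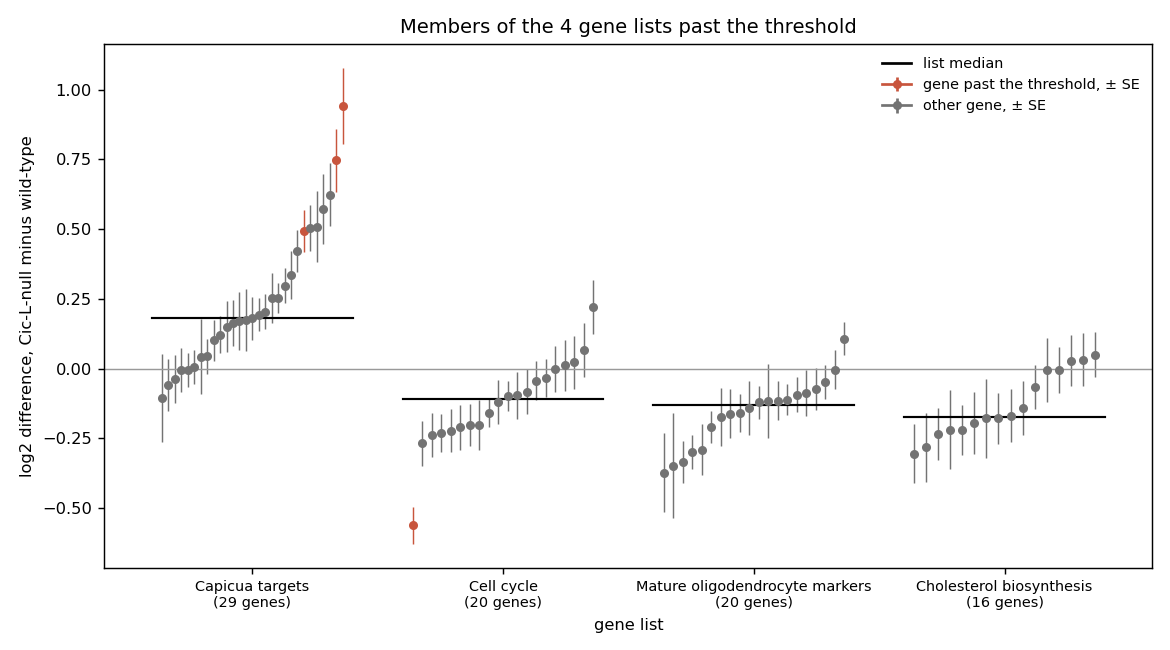
Log2 difference of Cic-L-null minus wild-type (vertical axis, ± SE) of each measured member of the 4 lists past the threshold (horizontal axis), with black lines at the list medians of 0.18, -0.11, -0.13 and -0.17. Coloured points mark genes past the threshold over all genes, which are Dusp4, Per2, Dusp6 and Top2a.

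Of the 25 lists, these 4 passed with the preset correlation, 1 higher and 3 lower, 0 passed with an estimated correlation, and 9 had an unadjusted p under 0.05. With fry, which asks whether a list moves 1 way on balance, the Capicua targets (adjusted p = 0.0109) and the mature oligodendrocyte markers (adjusted p = 0.0303) passed, and the cell cycle (adjusted p = 0.0796) and cholesterol lists (adjusted p = 0.668) did not.

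No list of neuronal markers passed. Purkinje cell markers had a median of 0.029 (adjusted p = 0.308 by camera, as for all lists here), with Lhx1 at 0.24 (SE 0.062) and the calcium channel gene Cacna1g at 0.19 (SE 0.061). Granule cell markers had a median of 0.031 (adjusted p = 0.125), and Reln, the secreted guidance protein of granule cells, differed by 0.32 (SE 0.064) and passed over the list alone, whereas the glutamate transporter gene Slc17a7 differed by 0.13 (SE 0.059). Interneuron markers had a median of 0.042 (adjusted p = 0.137), with Tfap2a at 0.30 (SE 0.078) and Gad1 at 0.13 (SE 0.058). Unipolar brush and deep nuclear neuron markers had a median of -0.014 (adjusted p = 0.902), with the unipolar brush cell gene Eomes at 0.47 (SE 0.13) and Spp1 at -0.41 (SE 0.10).

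Glial, vascular and immune markers other than those of mature oligodendrocytes did not pass as lists. Bergmann glia and astrocyte markers had a median of -0.030 (adjusted p = 0.125), and besides the fall of Fabp7, the cytochrome gene Cyp4f15 differed by 0.53 (SE 0.098). Adjusted over the list alone, 5 of the 22 fell and 1 rose. Oligodendrocyte precursor markers had a median of -0.0010 (adjusted p = 0.503). Microglia markers had a median of -0.014 (adjusted p = 0.902), with Fcrls at -0.44 (SE 0.15) and Ly86 at 0.25 (SE 0.11). The means of Fcrls, 5.74 in wild-type and 5.30 in Cic-L-null, lay below the dim limit of 6.21. Endothelial and pericyte markers had a median of -0.069 (adjusted p = 0.0507), with Itm2a at -0.39 (SE 0.090) and the tight junction gene Cldn5 at -0.27 (SE 0.070), the 2 members that fell over the list alone.

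Markers of neighbouring tissues gave no list call either. Meningeal fibroblast markers had a median of -0.068 (adjusted p = 0.45), with Igf2 at -0.22 (SE 0.068) and Col1a1 at -0.24 (SE 0.079). Choroid plexus and ependymal markers had a median of -0.030 (adjusted p = 0.45), with Kl at -0.45 (SE 0.20) and Sostdc1 at -0.58 (SE 0.28). Cic-L-null replicate 3 had the lowest value of each, 6.27 and 6.70, against mutant means of 6.94 and 7.48. Blood cell markers had a median of -0.015 (adjusted p = 0.906), with Alas2 at 0.50 (SE 0.16) and the globin gene Hbb-b1 at -0.45 (SE 0.22). The means of Hbb-b1, 6.02 in wild-type and 5.57 in Cic-L-null, lay below the dim limit of 6.21. Brainstem and forebrain markers had a median of -0.0018 (adjusted p = 0.902). The monoamine synthesis genes Th and Tph2 differed by 0.58 (SE 0.11) and 0.34 (SE 0.096), both past the threshold over the list alone. So was Hoxb3 at -0.31 (SE 0.091), named after its value was seen. Tph2, at 5.16 in wild-type and 5.49 in Cic-L-null, lay below the dim limit of 6.21 in both groups. Th lies on the chromosome of Cic, and its probe set 10569375 differed by 1.37 (SE 0.32).

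Signalling lists held single genes that stood out. The insulin-like and vascular growth factor list had a median of 0.068 (adjusted p = 0.125), with the receptor gene Igf1r at 0.42 (SE 0.084) as its member past the threshold over the list alone and Irs2 at 0.20 (SE 0.073). The extracellular matrix remodelling list had a median of -0.069 (adjusted p = 0.125), and the protease genes Plat at -0.25 (SE 0.050) and Mmp14 at -0.33 (SE 0.092) fell over the list alone. Neuropeptides had a median of 0.0023 (adjusted p = 0.906), with Cck at -0.38 (SE 0.074) and Npy at -0.42 (SE 0.12) lower and Penk at 0.25 (SE 0.075), named after its value was seen, higher over the list alone. None of these 7 genes passed over all genes.

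Stress and activity lists did not pass. Immediate early genes had a median of -0.010 (adjusted p = 0.726), with Arc at -0.26 (SE 0.075) and Egr1 at -0.18 (SE 0.077). Glucocorticoid and fasting response genes had a median of 0.043 (adjusted p = 0.308), with Fkbp5 at 0.34 (SE 0.12) and Lcn2 at 0.36 (SE 0.13). Single mutant arrays stood high, Fkbp5 at 7.96 in Cic-L-null replicate 4 (mutant mean 7.60) and Lcn2 at 6.37 in Cic-L-null replicate 2 (mutant mean 5.95). The amino acid and endoplasmic reticulum stress list had a median of -0.0050 (adjusted p = 0.760), with Ddit3 at 0.33 (SE 0.12) and Asns at -0.29 (SE 0.12). The fall of Asns leaned on wild-type replicate 1, at 11.23, where the other wild-type arrays lay from 10.64 to 10.69. Interferon response genes had a median of 0.035 (adjusted p = 0.45), with Isg15 at 0.25 (SE 0.075) and Ifit3 at 0.38 (SE 0.11). Mitochondrial respiratory chain genes had a median of -0.018 (adjusted p = 0.661), with Cycs at -0.14 (SE 0.070) and Sdha at -0.11 (SE 0.056).

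The Capicua and ataxin-1 complex list had a median of 0.041 (adjusted p = 0.619) and a mean of -0.060, which differ in sign because of Cic, and Rora, a nuclear receptor that binds ataxin-1, differed by 0.16 (SE 0.054). The 10 reference genes, not tested as a set, had a median of -0.040, with Rpl13a at -0.34 (SE 0.067). Among the 6 sex-linked genes, also not tested as a set, the median difference was 0.47, from Eif2s3y at 1.44 (SE 1.63) and Uty at 1.17 (SE 1.37) to Xist at -1.43 (SE 1.54). Kdm5d differed by 0.94 (SE 1.02), Eif2s3x by -0.13 (SE 0.12) and Kdm6a by -0.0086 (SE 0.11).

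Genes that neighbour Cic are of interest because the chromosome segment around an altered gene often stays that of the stem cell strain. Of 618 measured genes within 20 Mb of Cic, 3 were called, against 25 of 19681 elsewhere (odds ratio 3.84, Fisher's exact p = 0.0524). These 3 were Cic, Klk6 and Pafah1b3, a lipid hydrolase subunit gene that rose by 0.41 (SE 0.057) and was named after its value was seen. Cic is the altered gene, so its own call adds to the excess by design. Without it, 2 of 617 genes within 20 Mb were called (odds ratio 2.56, Fisher's exact p = 0.198). Within 10 Mb, Cic included, the odds ratio was 3.93 (Fisher's exact p = 0.101). Over the whole chromosome, 6 of 1780 genes besides Cic were called against 21 of 18518 on others (odds ratio 2.98, Fisher's exact p = 0.0268). The tests without Cic and of the whole chromosome were chosen after the data were seen.

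Single probe sets on that chromosome showed larger differences than whole genes. The only probe set past the threshold among 241576 was 10553542 of Luzp2, which fell by 3.21 (SE 0.20, adjusted p = 0.0456), where 16418 had an unadjusted p under 0.05. Probe sets that fell by more than 1 log2 unit with no overlap between the groups made up 0.329% of those within 20 Mb of Cic and 0.332% of those on the rest of its chromosome, Cic itself left out, against 0.0832% on other chromosomes. Rises of that size made up 0.123%, 0.0831% and 0.0858%. The 52 falls lay in 44 genes, and 23 of the 52 lay among the genes ranked 400 to 500 after Cic in order along the chromosome. Probe sets of Uevld at -4.22 and Gtf2h1 at -2.42, named after their values were seen, showed 2 of the largest falls. The Luzp2 call among probe sets was lost without wild-type replicates 1, 2 or 3 and without Cic-L-null replicates 1, 2, 3 or 4, each left out alone, and remained without wild-type replicate 4. Without wild-type replicate 4 the count was 3, and without wild-type replicate 1 it was 1.

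**Figure D4:**
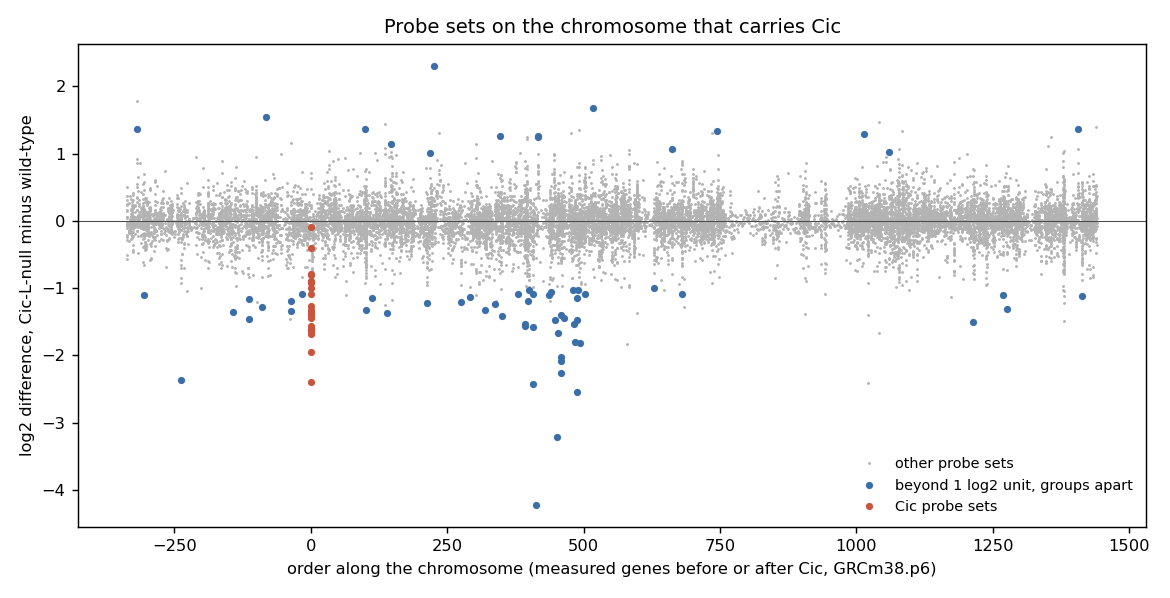
Log2 difference of Cic-L-null minus wild-type (vertical axis) of each probe set on the chromosome that carries Cic, placed by the order of 1780 measured genes in GRCm38.p6 relative to Cic at 0 (horizontal axis). Large points mark Cic probe sets and probe sets beyond 1 log2 unit whose groups do not overlap, with 52 falls and 15 rises besides Cic.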

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

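Within each group of 4 arrays, single arrays that lay far from the other 3 were sought among the named genes, the Cic probe sets and the array medians, and 23 of 218 groups held one. Chance gives about 1 in 20, or 10.9. The tests in this part were set before their results were seen, except those against the smallest p of any of the 25 lists.

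The departures with the largest gaps in log2 units were sex-linked. Among the mutants, Cic-L-null replicate 3 had Xist at 10.55 (next highest 5.19) and Kdm5d at 5.26, Eif2s3y at 4.19 and Uty at 4.22, where the next lowest values were 8.69, 9.70 and 8.90. The same array had the highest values of Dbp, 9.86, and Itm2a, 10.08, among the mutants and the lowest of Cic probe set 10551081, 8.58.

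Wild-type replicate 1, whose label alone names its own extraction kit, had the highest wild-type values of Etv1 (11.52), Etv5 (8.78), Gad1 (11.53) and Asns (11.23). Wild-type replicate 2 had the lowest wild-type value of Klk6, 7.61. Wild-type replicate 4 lay apart for 4 Cic probe sets, with 8.47 for 10551081, below the others, and 9.76 for 10551083, 9.81 for 10551094 and 10.01 for 10551101, above them. Cic-L-null replicate 2 had the highest mutant values of Etv4 (8.32), Lcn2 (6.37), Ifit3 (6.66), Sdha (11.31) and Cic probe set 10551093 (8.91). Cic-L-null replicate 4 had the lowest mutant values of Top2a (5.06) and Spp1 (6.97).

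The comparison of groups was set against the 35 ways to split the 8 arrays into 4 and 4, the real one included. For the 28 called genes, 1 of the 35 splits gave as many, the real one, and the highest count of the others was 1. The real split thus stood apart, although 1 of 35 is the smallest share this test can give. The test does not separate the mutation from any other difference between the groups. For probe sets, 8 of the 35 splits called at least the 1 of the real split and the highest other count was 4, so chance cannot be excluded. For the number of gene lists, 23 of the 35 splits gave at least the 4 of the real split and the highest other count was 11, so that number by itself cannot be told from chance. Taken list by list, 1 of the 35 splits gave a camera p as small as the real one for the Capicua targets (7.17e-17, smallest other 2.22e-10), and likewise 1 for the mature oligodendrocyte markers (1.16e-07, smallest other 3.63e-06). As both lists stood out among 25, they were also set against the smallest p of any list in each split, which was 1.07e-10 at the lowest among the other splits. For the Capicua targets only the real split gave a p as small, 1 of 35, which is the smallest share this test can give. That list may rest in part on work that used these samples, so its rise may not be independent support. For the mature oligodendrocyte markers 12 of the 35 splits did, so chance cannot be excluded for that list. Taken by its own p, the cell cycle list had 2 splits with one as small (4.71e-06, smallest other 4.88e-07) and the cholesterol list had 13 (0.000960, smallest other 3.84e-10), so chance cannot be excluded for them either.

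The first pattern is the fall of single probe sets on the chromosome of Cic. Lower expression of the linked genes as a whole is argued against, since the median over genes within 20 Mb of the gene's median probe set difference was -0.018. In the 14 genes within 20 Mb with a fall beyond 1 log2 unit, 12 of which had just 1 such probe set, the median of the other probe sets was -0.17, against -0.058 in genes with such falls on other chromosomes. Over the whole chromosome, 38 of 44 such genes had just 1 such probe set, and the median of the other probe sets was -0.080. These medians leave out the large falls, so values near 0 are in part built in and cannot decide for sequence variants. By their count per gene, the large falls sit mostly in single probe sets, and sequence variants may lie under those probes. Whether these belong to a stem cell segment linked to Cic stays open, since the falls do not cluster at Cic. Among 885 probe sets of the 100 genes in order from Cic onwards, those of Cic left out, there were 0 such falls, against 4 among 739 of the 100 genes before it, and 36 of the 52 lay beyond 20 Mb. The other probe sets of Klk6, and of Sergef and Luzp2 farther from Cic, were also lower, with medians of -0.62, -0.79 and -0.30. A change of these transcripts thus stays open. The labels give all 8 animals the same mixed background of Swiss Webster (CD-1) but not the stem cell strain. Cic itself, with 21 of 21 probe sets lower, is not a case of single probes.

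The second pattern is the fall of mature oligodendrocyte markers. A larger number of males among the mutants is argued against, since with the Y-linked covariate the list's median was 1.15 times that without it, and so is a single deciding array, since the smallest median with 1 array left out was 0.927 of the full one. A lower share of the whole oligodendrocyte lineage cannot be told apart from a change in mature cells alone. The shared lineage genes Olig1, Olig2 and Sox10 had a median of -0.062, between 0 and the cut set in advance for a lower share. Their SE of 0.069 to 0.090 exceed that median in size, so these genes cannot decide. A chance split also stays open, as given above, beside an effect of the mutation on myelin genes.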

How the results depend on the processing

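All alternatives were fixed before the data were examined, except the tests of genes near Cic without Cic itself, of its whole chromosome, of the calls without that chromosome, and of the first residual component, which took the place of a surrogate variable from sva that was not run. The count of 28 called genes lay between 26 and 42 with probe sets above the dim limit, quantile normalisation, median centring, cyclic loess or the first residual component. It was 2 with the median of the probe sets, 12 with their brighter part, 69 among genes above the dim limit, 130 with trend and robust variance, 54 with array weights, 18 with the Y-linked covariate, 96 at an adjusted p under 0.10 and 0 with unmoderated tests, where 1885 genes had an unadjusted p under 0.05 by limma. Why each count moved was not tested, save that the looser threshold takes more genes. With 1 array left out the count ranged from 0 to 37, over 3 instead of 4 arrays in a group, and without the chromosome of Cic it was 19. Over all alternatives, 268 of 501 values of the named genes among the 28, Cic left out, kept direction and call. Another 233 kept the direction only and 0 reversed. With 1 array left out no reversal was possible for the called genes, Cic included, since their groups do not overlap.

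Cic kept its direction throughout, with -1.23 without Cic-L-null replicate 2, and -1.32 to -1.11 over single arrays left out. Its adjusted p ranged from 0.000538 to 0.157 and was over the threshold without that array (0.0589), with unmoderated tests (-1.25, 0.157) and with the replicate block (-1.25, 0.0564). Used as a replicate block, the numbers in the titles gave 0 called genes and 0 called probe sets, and the same 4 of 25 lists. Same-numbered arrays correlated in their deviations at 0.000325 to 0.219, 2 of 4 pairs above 0.1, and 4 of the 8 arrays correlated best with their own number. These values do not settle whether the numbers pair animals. The main fit, set in advance, did not pair them.

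The 4 list calls became 0 with an estimated correlation and 2 with fry, and lay between 3 and 6 otherwise. The 1 called probe set became 5 above the dim limit and 0 to 3 with 1 array left out. The odds ratio of calls near Cic was 3.93 within 10 Mb, 2.56 without Cic and 2.98, past the threshold, for the whole chromosome. Reversed differences belonged to genes near 0 or sex-linked: Uty -0.040 and Kdm6a 0.068 with the Y-linked covariate, Atxn1l between -0.018 (without wild-type replicate 2) and 0.042 and Kdm6a between -0.095 and 0.070 with 1 array left out. The Y-linked covariate is a mean that includes Uty, so a difference of Uty near 0 with it follows by construction. For the other reversals the cause was not tested. Signal over background limits the dimmer genes, since 14010 of 20352 lay above the olfactory receptor limit.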

Other observations

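The clock genes formed a further pattern, which no list had covered. Besides Nr1d1, Per2, Per3 and Dbp (median difference 0.65), the 6 other genes with the same daily phase were all above 0, with a median of 0.35. Among them Bhlhe41 differed by 0.50 (SE 0.13), Ciart by 0.47 (SE 0.13), Nr1d2 by 0.37 (SE 0.13) and Tef by 0.34 (SE 0.066), while Per1 differed by 0.26 (SE 0.16) and Hlf by 0.060 (SE 0.056). The 5 genes of the opposite phase were all below 0. Arntl differed by -0.41 (SE 0.15), Npas2 by -0.40 (SE 0.086), Cry1 by -0.22 (SE 0.057), Clock by -0.21 (SE 0.068) and Nfil3 by -0.16 (SE 0.094). The tests of the 4 and of the 6 genes were chosen after values of some of them were seen, and that of the 5 before theirs were; none of the 11 was called over all genes, and Tef came closest with an adjusted p of 0.0901 by limma. Tested with camera, the unadjusted p was 6.76e-07 for the 6 genes and 3.03e-06 for the 5, or 0.0205 and 0.00312 with an estimated correlation.

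A larger number of males among the mutants is argued against, since with the Y-linked covariate the median of the 4 called genes was 1.04 times that without it. A different clock phase at collection predicted that genes of the opposite phase would be lower, and their median was -0.22. Collection at different points of the daily cycle would give such a fall, by time of day or by a shifted clock of the mutants. The test cannot single out that reading. Nr1d1 represses Arntl, so a rise of Nr1d1 from another cause could lower Arntl too. The labels give no time of collection, so these alternatives stay open. Per2 is also on the Capicua target list. Whether its rise comes from the mutation of Capicua or from a different clock phase was not tested, nor whether it leads to the other differences.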
